A study of Mus musculus with 9 samples.

How the data were processed

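RNA sequencing libraries from 9 samples of mouse CD8+ T cells were analysed, 3 in each of 3 groups: co-cultured and DsRed-positive (MitoPositive), co-cultured and DsRed-negative (MitoNegative), and cultured alone (monoculture). Per the labels, total RNA was extracted, ribosomal RNA was depleted, and co-culture with DM5 stromal cells lasted 36 h; the sample titles carry a time of 0 h, whose meaning the labels do not explain. The deposited table of raw counts holds 55520 entries, of which 99 are spike-in controls with 0 counts in the 9 libraries and 55421 are genes. The authors' processing notes name bcl2fastq, cutadapt, STAR 2.7, featureCounts, DESeq2 and the genome build GRCm38 behind these counts. A second deposited table holds the counts of 16163 genes, each equal to its raw counts; its filter was not stated, and the lowest total among its genes was 27 while the highest total among removed genes was 80. Gene coordinates in bases, as deposited with the counts, were those of GENCODE M21 for the 54673 identifiers with version found there. The annotation release and the strandedness of counting were not given in the sources used here, so reads from overlapping genes on opposite strands cannot be told apart.

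Raw counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15711 genes and at least 99.96% of the counts of each library. Library sizes were scaled by trimmed mean of M-values (TMM). The 9 libraries were fitted together by group with robust quasi-likelihood, which left 6 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Total counts per library ranged from 53546152 to 74722832. The 3 comparisons were MitoPositive against MitoNegative and each of these against monoculture. On simulated data with 200 changed genes in each of 5 simulations, the MitoPositive against MitoNegative fit found 13.7% of genes changed 1.25-fold, 47.8% of those changed 1.5-fold and 66.7% of those changed 2-fold, and 5.96% of its calls were false.

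Gene lists fixed before the data were examined covered mitochondrially encoded proteins, the nuclear respiratory chain, mitochondrial ribosome, mitochondrial biogenesis and dynamics, glycolysis, the citric acid cycle, fatty acid oxidation, cholesterol and lipid synthesis, the ATF4, unfolded protein, hypoxia and oxidative stress responses, proliferation, effector and cytotoxic genes, naive and stem-like memory genes, inhibitory receptors and exhaustion, T-cell receptor activation, interferon response, apoptosis and p53, adhesion, cytoskeleton and nanotubes, chemokine and cytokine receptors, the cytosolic ribosome, RNA composition and histones. Marker lists covered CD8+ T cells, stromal, myeloid, dendritic and class II, B, CD4+ T and natural killer cells. A list of erythroid and platelet markers had 1 measured member of 12 and was not tested. The 31 lists with at least 3 measured members were tested by camera (limma 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and by fry. Members were counted by adjusted p over 15711 genes and adjusted over the list alone. Each gene identifier matched by symbol counted as a member, so a symbol held by more than 1 identifier, such as Ddit3, can count more than once.

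Genes to be named were chosen by a rule set before the data were examined. For MitoPositive against MitoNegative it took up to 10 rises and 10 falls with the largest change among genes that passed the test, had a mean log2 CPM of at least 1 and an assigned symbol, and did not overlap between the groups. For each comparison with monoculture it took 6 and 6. It also took up to 3 passing members of each list, and Cd8a, Ptprc, Tcf7, Gzmb, Pdcd1, Tox, Ppargc1a, Tfam, Tln1, Tln2, mt-Co1 and Col1a1. For a gene at 0 counts in a group the fold was computed against a floor of 3 counts over the group.

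Whether replicate letters pair libraries across groups was tested by the correlation of same-letter residuals, with a threshold of 0.1. Between MitoPositive and MitoNegative it was 0.402, 0.339 and 0.459 for B, C and D. Between MitoNegative and monoculture it was 0.213, 0.153 and 0.111, so in both the letters were taken as pairs. The main fit by group has no term for the letter, so results given without the block do not use these pairs. Between MitoPositive and monoculture the correlation was 0.248, 0.0521 and 0.163, so by the threshold those were not. This does not show that they are unpaired, since pairs in both other comparisons imply pairs here as well. A fit with the letter as a block left 4 residual degrees of freedom; where it changed the call of a list or moved the number of its called genes by more than 1.5-fold in the comparisons whose letters pair, its values stand beside the result. For MitoPositive against monoculture most of its values stand with the alternatives.

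Alternatives were DESeq2's size factors (RLE), total counts as the scale, no filter, the genes of the authors' filtered table, DESeq2 1.42.0 with its Wald test, limma voom, a fit of the compared groups alone, the letter as a block, removal of mitochondrially encoded genes, and leaving out each library or letter. Shared calls of both monoculture comparisons were set beside 20 simulations, each of which drew 9 libraries at their real depths from the monoculture means, with no effect of the letter. Shares of counts were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1.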

Results

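Gene expression was measured by sequencing of ribosomal RNA depleted total RNA in 9 libraries of mouse CD8+ T cells from the spleens of Pmel Ly5.1 mice, which carry a transgenic T-cell receptor. In 6 libraries the T cells had spent 36 h in co-culture with DM5, an immortalised line of bone marrow stromal cells whose mitochondria carried the red fluorescent protein DsRed. The co-cultured T cells had then been sorted into DsRed-positive cells (MitoPositive, 3 libraries) and DsRed-negative cells (MitoNegative, 3 libraries). The other 3 libraries came from T cells cultured without stromal cells (monoculture). Each group had replicates lettered B, C and D. Total counts per library were 74722832, 53546152 and 70379560 in MitoPositive, 67748610, 70750494 and 66068215 in MitoNegative, and 60551510, 59264244 and 64081012 in monoculture, in the order B, C and D. The replicates of each group differed from one another by more than sampling noise, with a chi-square per degree of freedom of 18.3 to 64.3. The labels did not state that the letters were separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Across genes, the first principal component of log2 CPM (counts scaled to the normalised library size) held 65.7% of the variance and separated monoculture (64.8 to 70.7) from both co-cultured groups (-43.3 to -25.5). The second held 9.09% and followed the letters, for which the main test below has no term. Unless stated otherwise, values below are log2 fold changes or folds with the standard error (SE) of the log2 fold change, n = 3 per group, and adjusted p-values from edgeR's quasi-likelihood test over 15711 genes; levels are mean CPM ± SD.

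The comparison of MitoPositive with MitoNegative cells asked how T cells that carried labelled stromal mitochondria differed from co-cultured T cells without the label. Among the 27 measured genes of the apoptosis and p53 list 3 targets of the tumour suppressor p53 rose: Cdkn1a, a cyclin-dependent kinase inhibitor, rose 1.73-fold (log2 0.79 ± 0.121), Phlda3 rose 1.40-fold (0.49 ± 0.054) and Zmat3 rose 1.33-fold (0.42 ± 0.0539). Prdm1, which encodes the effector regulator Blimp-1, rose 1.76-fold (0.81 ± 0.13), and Tnfsf4, which encodes the costimulatory ligand OX40L, rose 1.78-fold (0.83 ± 0.123). The 12S ribosomal RNA of the mitochondrion, mt-Rnr1, fell 2.04-fold (-1.03 ± 0.0887). It stood at 3840 ± 264 CPM in MitoNegative and 1880 ± 102 CPM in MitoPositive cells, against 580 ± 44.8 CPM in monoculture. A difference in ribosomal RNA depletion between the libraries was not excluded. None of the 13 mitochondrially encoded protein genes and none of the 75 measured nuclear genes of the respiratory chain passed edgeR's test.

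In the whole comparison 26 genes passed an adjusted p of 0.05, 14 higher and 12 lower in MitoPositive cells, and 1646 genes had an unadjusted p under that value. With the replicate letter as a block 367 genes passed, 198 higher and 169 lower, and these included the 26. A fit of the sorted groups alone with the block called 2810 genes, while the block over all groups called 0 without letter B or C. The number of genes that differ thus depended strongly on the fit. List members called with the block, as given below, come from the fit of all 9 libraries. The share of higher genes among the calls was 53.8%, against 66.7% of 15 calls with DESeq2's size factors and 71.4% of 14 calls with total counts as the scale. The count varied with the library left out, falling for some and rising for others. Without MitoNegative B, MitoNegative C or MitoPositive C, 1 gene passed each time, which was mt-Rnr1; 3 passed without MitoPositive B, 10 without monoculture C, 13 without MitoNegative D, 51 without monoculture B, 105 without MitoPositive D and 120 without monoculture D. Without all libraries of letter B, or of letter C, edgeR called 0 genes (996 and 580 with an unadjusted p under 0.05), and without letter D it called 120.

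The largest rise among the genes named by the fixed rule was that of Serpine2, a secreted protease inhibitor, from 175 ± 19.6 to 320 ± 50.9 CPM (0.87 ± 0.134, adjusted p = 0.0464; chromosome 1, positions 79794197 to 79861180 in GRCm38). Tnfsf4 stood at 29.0 ± 2.45 CPM in MitoNegative and 51.5 ± 4.52 CPM in MitoPositive cells (adjusted p = 0.046). Prdm1 stood at 6.31 ± 0.28 and 11.1 ± 1.76 CPM (adjusted p = 0.0464; chromosome 10, positions 44437177 to 44528501). Cdkn1a (ENSMUSG00000023067.14; chromosome 17, positions 29090976 to 29100727) stood at 108 ± 1.78 and 187 ± 22.9 CPM, against 4.65 ± 0.986 CPM in monoculture (adjusted p = 0.0464). Glipr1, a gene of the pathogenesis-related protein family, rose from 35.6 to 55.0 CPM (0.63 ± 0.0676, adjusted p = 0.00713). Smaller rises were those of Inka2 (0.50), Raph1 (0.48), Slamf7, a receptor of the SLAM family (0.46), and Icos, an inducible costimulatory receptor (0.40 ± 0.0624, from 96.5 to 127 CPM), with adjusted p-values of 0.046 to 0.0464.

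Among the genes that fell, Rnf144a, which encodes a ubiquitin ligase, went from 8.62 ± 0.731 to 4.21 ± 0.924 CPM (-1.03 ± 0.148, adjusted p = 0.046), and it stood at 43.0 ± 5.73 CPM in monoculture. Nsg2 fell by 0.73 (SE 0.0997, adjusted p = 0.0401) on the log2 scale. Smc4, a condensin subunit, fell by 0.58, Tbc1d4, a regulator of glucose transporter traffic, by a log2 change of -0.56, and Pik3ip1, an inhibitor of phosphoinositide 3-kinase, by -0.50. Ighm, the heavy chain of immunoglobulin M and a B-cell marker, changed by -0.52, from 388 ± 43.7 to 271 ± 10.8 CPM, against 630 ± 36 CPM in monoculture. Arl5c (-0.48), Coro7 (-0.35) and Ifnar2, a chain of the type I interferon receptor (-0.32), also fell, with adjusted p-values of 0.046 to 0.0496. The remaining 5 of the 26 genes lay outside the naming rule and were chosen after their values were seen: Pparg (2.62, from 0.122 to 0.766 CPM), Agpat5 (0.34), the predicted gene Gm42427 (3.36, under 1 CPM in each group), A930002I21Rik (-0.56) and the pseudogene Bambi-ps1 (-0.70).

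**Figure D1:**
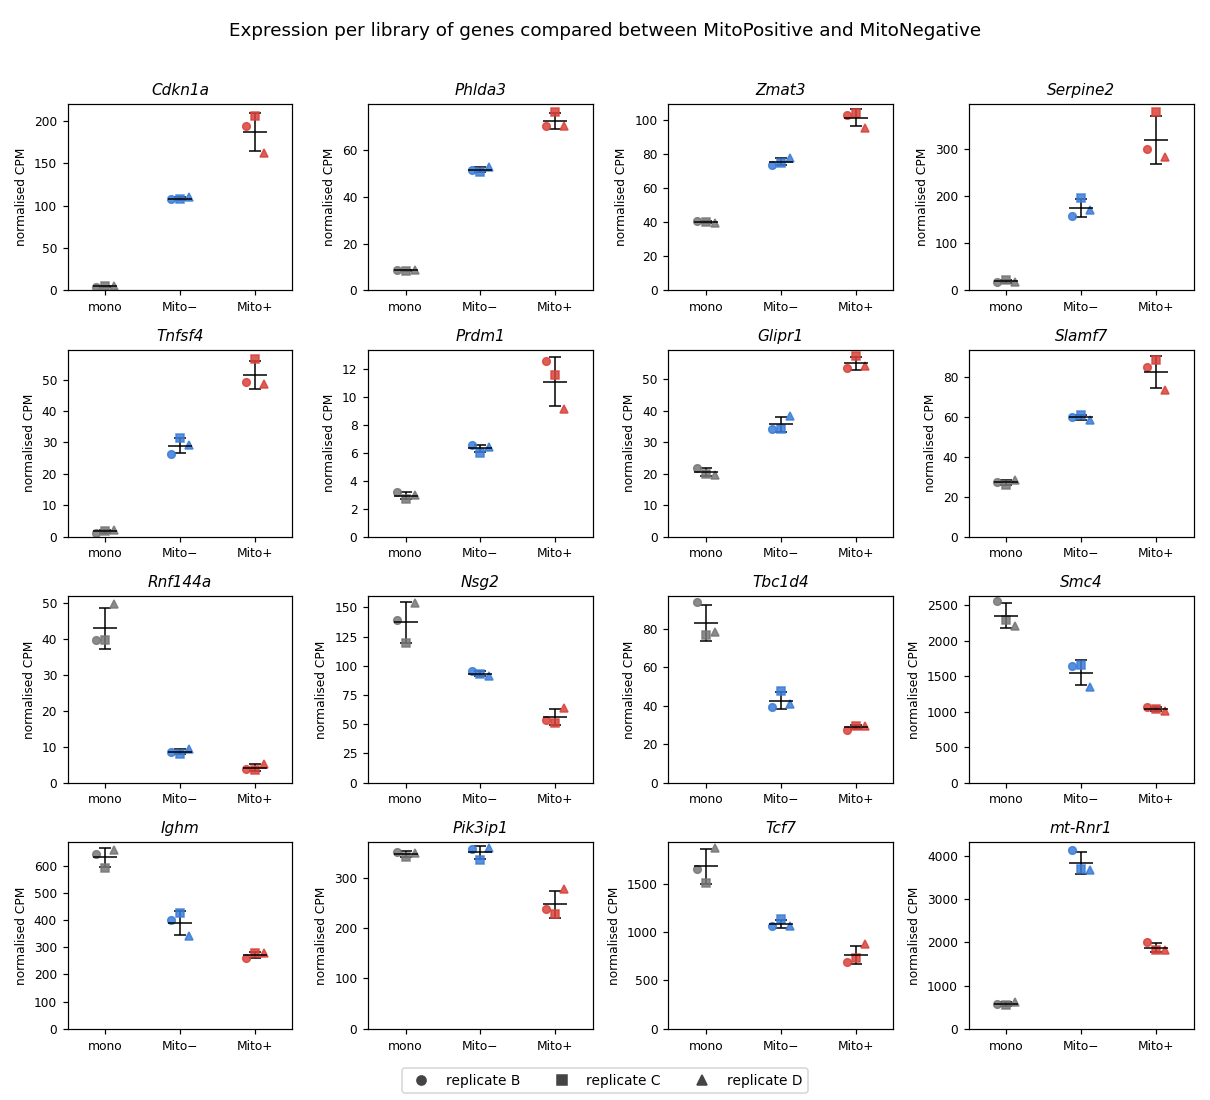
Normalised CPM (vertical axes from 0) of 16 genes in monoculture, MitoNegative and MitoPositive libraries; markers are single libraries by replicate letter, and the black lines are the mean and SD of 3. The 3 MitoPositive libraries lie above the 3 MitoNegative libraries for Cdkn1a, Phlda3 and Serpine2 and below them for mt-Rnr1 and Rnf144a.

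Of the 27 measured genes of the apoptosis and p53 list, 3 rose (Cdkn1a, Phlda3 and Zmat3), none fell and 24 did not pass. With DESeq2's size factors 2 rose, while DESeq2 called 7 and limma voom 4. Adjusted over the list alone, 9 were higher and 1, Gadd45a (-0.46), was lower. With the block 6 were higher, the others being Bax (0.30 ± 0.0556), Tnfrsf10b (0.49 ± 0.0945) and Ccng1 (0.29 ± 0.064). The list as a set was higher by camera's competitive test (adjusted p = 1.44e-06 over 31 lists), and its adjusted p = 0.223 with an estimated correlation.

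None of the 22 measured genes of the naive and stem-like memory list passed over all genes, where 14 had an unadjusted p under 0.05, DESeq2 called 9 and limma voom 1. Adjusted over the list alone 3 were higher and 11 lower, and with the block 1 was higher and 9 lower. The lower ones with the block included Klf2, a regulator of lymphocyte egress (-0.98 ± 0.154), Myb (-0.69 ± 0.0908), Tcf7, which encodes the stem-like memory regulator TCF-1 (-0.51 ± 0.0906), Id3 (-0.49 ± 0.0878), S1pr1 (-0.35 ± 0.0724) and Slamf6 (-0.33 ± 0.0662), and the higher one was Cd28 (0.33 ± 0.0588). Tcf7 stood at 1080 ± 41.3 CPM in MitoNegative and 765 ± 94.3 CPM in MitoPositive cells, with an adjusted p of 0.069 without the block and 0.0214 with it. The set was lower by camera (adjusted p = 4.32e-08), with adjusted p = 0.0961 with an estimated correlation.

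Of 30 measured effector and cytotoxic genes, 1 rose, Prdm1, and 0 did with total counts as the scale. An unadjusted p under 0.05 was reached by 11, DESeq2 called 7 and limma voom 2. Adjusted over the list alone 6 were higher and 1, Klrd1 (-0.32), was lower. With the block 4 were higher: Prdm1, Gzmc (0.87 ± 0.1), the interleukin 2 receptor chain Il2ra (0.70 ± 0.137) and Zeb2 (0.51 ± 0.0898); reads of Gzmc are uncertain because granzyme genes resemble one another. Gzmb, which encodes granzyme B, stood at 499 ± 68.8 CPM in MitoNegative and 791 ± 159 CPM in MitoPositive cells and did not pass (0.66 ± 0.314, adjusted p = 0.535). Camera's adjusted p for the set was 9.88e-05, and adjusted p = 0.305 with an estimated correlation. None of the 24 chemokine and cytokine receptors passed (10 with an unadjusted p under 0.05, 5 by DESeq2, 2 by limma voom), 5 were higher and 1 lower adjusted over the list alone, and with the block Ccr4 (0.71 ± 0.101), Cxcr6 (0.60 ± 0.115), Il2rb (0.42 ± 0.0877) and Il12rb2 (0.41 ± 0.065) were higher. Their set had a camera adjusted p of 9.73e-07, and adjusted p = 0.0961 with an estimated correlation. Of 29 genes of T-cell receptor activation, 1 rose, Icos, and 0 did with total counts as the scale. DESeq2 called 4 and limma voom 1. With the block Fosl2 (0.65 ± 0.0998), Dusp5 (0.52 ± 0.0975) and Myc (0.29 ± 0.0532) were higher as well and Rel (-0.38 ± 0.0818) was lower. The set did not pass (camera adjusted p = 0.232), with a median of -0.05 and a mean of 0.02.

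Of the 22 inhibitory receptor and exhaustion genes none passed (7 with an unadjusted p under 0.05, 3 by DESeq2, 0 by limma voom), 2 were higher adjusted over the list alone, and with the block Pdcd1, which encodes PD-1 (0.41 ± 0.0727, adjusted p = 0.0213), and Cd200r1 (0.95 ± 0.175) were higher. Pdcd1 without the block had 0.42 ± 0.189 and an adjusted p of 0.497, and Tox, a regulator of exhaustion, had -0.29 ± 0.113 and 0.394. The set had a camera adjusted p of 0.0274, and adjusted p = 0.647 with an estimated correlation. None of 37 adhesion, cytoskeleton and nanotube genes passed (11 with an unadjusted p under 0.05, 4 by DESeq2, 0 by limma voom), 4 were higher adjusted over the list alone, and with the block Vim, the intermediate filament vimentin (0.64 ± 0.0674), the filopodial motor Myo10 (0.61 ± 0.0953), Tubb6 (0.54 ± 0.12) and Myo1g (0.26 ± 0.0551) were higher. The set had a camera adjusted p of 0.0136, and adjusted p = 0.713 with an estimated correlation. Neither integrin-binding talin passed: Tln1 differed by -0.0030 ± 0.0667 (adjusted p = 0.993, with a sign that turned under several settings) and Tln2 by 0.30 ± 0.178 (adjusted p = 0.622).

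By edgeR no gene was called among the 13 mitochondrially encoded protein genes (0 with an unadjusted p under 0.05), 75 respiratory chain genes (4), 77 mitochondrial ribosome genes (5), 42 genes of mitochondrial biogenesis and dynamics (3), 22 genes of the citric acid cycle (1) and 24 genes of fatty acid oxidation (2). DESeq2, limma voom, the block over all 9 libraries and the adjustment over each list alone also gave 0 in each. These lists were not counted in the fit of the sorted groups alone with the block. Their median log2 fold changes were -0.08, 0.05, 0.05, 0.01, 0.03 and 0.04. As sets, the respiratory chain and the mitochondrial ribosome were higher by camera (adjusted p = 0.0307 for each), and this call ended with the block (0.0638 and 0.0571) and with an estimated correlation (adjusted p = 0.83 for each). The subunit mt-Co1 of cytochrome oxidase stood at 14400 ± 684 and 12300 ± 1360 CPM (adjusted p = 0.517), and Tfam, a factor of mitochondrial transcription, at 71.0 ± 5.95 and 65.3 ± 3.83 CPM (adjusted p = 0.606). Ppargc1a, the coactivator PGC-1 alpha, was below the filter with 0 to 2 counts per library. The counts of mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l stood far below mt-Co1, with mt-Atp6 at 11.5 CPM in MitoPositive cells, and are uncertain, because reads shared with near-identical nuclear copies may not have been counted.

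Of 25 glycolysis genes none passed (4 with an unadjusted p under 0.05, 2 by DESeq2, 0 by limma voom); hexokinase 2, Hk2, was higher adjusted over the list alone and with the block (0.66 ± 0.0825). The set did not pass (camera adjusted p = 0.0864). None of 20 hypoxia targets, 20 genes of the unfolded protein response and 33 genes of the ATF4 stress response passed (6, 4 and 4 with an unadjusted p under 0.05; 2, 2 and 1 by DESeq2; 0, 1 and 0 by limma voom). With the block Ero1l (0.27) and Fam162a (0.31) of the hypoxia list and the chaperones Sdf2l1 (0.40) and Hsp90b1 (0.33) were higher. The ATF4 list split with the block into Stc2 (0.58), higher, and Ddit3 (-0.35), lower. The value of Ddit3 is that of ENSMUSG00000025408 and is uncertain, because more than 1 identifier holds this symbol. The hypoxia and unfolded protein sets were higher by camera (adjusted p = 0.0274 and 8.1e-05), with adjusted p = 0.51 and 0.35 with an estimated correlation. None of 39 interferon response genes passed (4 with an unadjusted p under 0.05, 0 by DESeq2 and by limma voom); with the block Ifi44 (-0.63 ± 0.1), Iigp1 (-0.40 ± 0.0729) and Stat2 (-0.33 ± 0.0722) were lower. That set was lower by camera (adjusted p = 0.000112), with adjusted p = 0.764 with an estimated correlation.

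Markers of other cell types were mostly uncalled between the sorted groups. None of 38 stromal markers passed (2 with an unadjusted p under 0.05, 0 by DESeq2 and by limma voom), with a median of -0.16 and, with the block, 1 lower member, Nt5e (-0.58 ± 0.0928). The collagen gene Col1a1 stood at 4.41 ± 1.95 and 4.30 ± 2.03 CPM (adjusted p = 0.985). Of 14 B-cell markers 1 fell, Ighm (camera adjusted p = 0.00792, and adjusted p = 0.764 with an estimated correlation). None of 5 natural killer cell markers passed (2 with an unadjusted p under 0.05, 1 by DESeq2, 0 by limma voom), and with the block Klre1 (-1.23 ± 0.171) was lower, from 2.92 to 1.23 CPM (camera adjusted p = 0.00302, and adjusted p = 0.35 with an estimated correlation). Cd8a stood at 1270 ± 70.9 and 1200 ± 63.2 CPM (adjusted p = 0.818), and the leukocyte antigen Ptprc at 2250 ± 13.8 and 2350 ± 94.5 CPM (adjusted p = 0.858). In the list of RNA composition genes mt-Rnr1 fell and mt-Rnr2, the 16S ribosomal RNA, was lower with the block (-0.49 ± 0.0881); the list's median was 0.02 while its test was negative (camera adjusted p = 0.000153, and adjusted p = 0.305 with an estimated correlation). The 2 mitochondrial ribosomal RNAs made up 0.511% ± 0.047 of counts in MitoPositive, 0.825% ± 0.034 in MitoNegative and 0.224% ± 0.019 in monoculture (SD, n = 3; exact two-sided permutation p = 0.1 for each pair, the smallest that 3 against 3 allows; adjusted p = 0.257 over 18 tests).

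Of the remaining lists, no gene passed edgeR's test among 29 genes of cholesterol and lipid synthesis, 22 of oxidative stress, 32 of proliferation, 81 cytosolic ribosomal proteins, 16 CD8+ T-cell markers, 12 myeloid, 10 dendritic and class II and 5 CD4+ T-cell markers and 24 histones. Those with an unadjusted p under 0.05 numbered 4, 5, 1, 1, 3, 1, 2, 2 and 2, DESeq2 called 2, 1, 0, 1, 2, 0, 1, 1 and 0, and limma voom called 1 gene, in the ribosomal list. With the block the sterol regulator Insig1 (-0.35 ± 0.0645), the antioxidant regulator Nfe2l2 (-0.29 ± 0.0502), Cd5 (-0.33 ± 0.0594) and Cd6 (-0.27 ± 0.0582) were lower, and Rps27l (0.36 ± 0.0618) and the class II gene H2-Eb1 (0.40 ± 0.0715) were higher. Cytosolic ribosomal proteins (median -0.06) and histones (median -0.28) were lower as sets by camera (adjusted p = 0.0136 and 0.00629), with adjusted p = 0.83 and 0.533 with an estimated correlation. The dendritic and class II list had a median of 0.11 and a mean of -0.03 (camera adjusted p = 0.805).

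In total camera called 16 of 31 lists, 9 higher and 7 lower; none held with an estimated correlation (smallest adjusted p = 0.0961), none passed fry, and 14 were called with the block. Among the 26 genes called between the sorted groups, 23 had the same sign in MitoNegative against monoculture and 19 of these were called there. Of the other genes mt-Rnr1 was called in the opposite direction. Among the 367 genes called with the block, 263 had the same sign, 210 of them called, and 60 were called in the opposite direction. Noise in the MitoNegative libraries, which both comparisons use, favours opposite directions.

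The comparison of MitoPositive cells with monoculture asked how T cells with labelled stromal mitochondria differed from T cells that had met no stromal cells. Of the named genes of T-cell effector function, the cytokine Ifng rose 35.2-fold (5.14 ± 0.497) and Gzmb 21.1-fold (4.40 ± 0.362). The p53 target Cdkn1a rose 40.3-fold (5.33 ± 0.151). Of the naive and stem-like memory genes, 15 of 22 fell and 2 rose. Klf2 was 29.4-fold lower (-4.88 ± 0.205) and Id3 5.16-fold lower (-2.37 ± 0.148). Transcripts of stromal cells, near 0 in monoculture, were present at low levels, such as Fn1, the matrix protein fibronectin, at 7.66 CPM against 0.055 CPM.

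In this comparison 6637 genes passed, 3504 higher and 3133 lower, of which 1410 and 529 differed by more than 2-fold. Without the libraries of letter C the count was 4122. Camera called 17 of 31 lists, 12 higher and 5 lower; with an estimated correlation the naive and stem-like memory list and the apoptosis and p53 list held, each with adjusted p = 0.0463, and with the block as well neither did (adjusted p = 0.0623 for each).

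Of the 27 apoptosis and p53 genes 17 rose and 3 fell, and the same numbers came out adjusted over the list alone. Phlda3 rose 8.45-fold (3.08 ± 0.0602, adjusted p = 7.02e-11) and the death receptor Tnfrsf10b 4.45-fold (2.15 ± 0.115). Of 22 naive and stem-like memory genes 2 rose and 15 fell (2 and 16 adjusted over the list alone); Tcf7 fell 2.19-fold, from 1680 ± 180 to 765 ± 94.3 CPM, and Il6ra 3.28-fold (-1.71 ± 0.318). Of 30 effector and cytotoxic genes 18 rose and 3 fell (21 and 3 adjusted over the list alone), with Gzmc at 3.40 ± 0.23 (camera adjusted p = 1.17e-08, and adjusted p = 0.143 with an estimated correlation). Of 29 genes of T-cell receptor activation 17 rose and 3 fell, among the former the transcription factors Fosl2 (3.06 ± 0.133) and Fosb (2.81 ± 0.347), with a camera adjusted p of 2.65e-09 and adjusted p = 0.241 with an estimated correlation. Of 22 inhibitory receptor and exhaustion genes 13 rose and 2 fell: Havcr2, which encodes TIM-3, rose 10.4-fold, Entpd1, the ectonucleotidase CD39, 4.38-fold, and Pdcd1 4.15-fold, while Tox fell by 0.51 (SE 0.113) on the log2 scale (camera adjusted p = 0.000313, and adjusted p = 0.241 with an estimated correlation). Of 24 chemokine and cytokine receptors 15 rose and 5 fell, with Il12rb2 at 1.88 ± 0.0739 (camera adjusted p = 0.000146, and adjusted p = 0.143 with an estimated correlation).

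Of 25 glycolysis genes 16 rose and 1 fell (17 and 3 adjusted over the list alone). Phosphoglycerate kinase Pgk1 rose 4.77-fold and Hk2 4.03-fold (camera adjusted p = 1.81e-09, and adjusted p = 0.143 with an estimated correlation); reads of Pgk1 are uncertain because it has processed pseudogene copies. Of 20 hypoxia targets 10 rose and 2 fell, with Bhlhe40 8.21-fold and the growth factor Vegfa 7.78-fold higher (camera adjusted p = 0.000141, and adjusted p = 0.172 with an estimated correlation). Of 33 ATF4 stress response genes 25 rose and 1 fell, with the amino acid transporter Slc1a4 at 3.79 ± 0.262 and Chac1 at 3.23 ± 0.319 (camera adjusted p = 9.07e-12, and adjusted p = 0.241 with an estimated correlation). Of 20 genes of the unfolded protein response 11 rose and 1, Dnajc3 (-0.59), fell (camera adjusted p = 0.0435, and adjusted p = 0.605 with an estimated correlation). Of 22 oxidative stress genes 6 rose and 7 fell, with Osgin1 at 2.54 ± 0.126 and the haem oxygenase Hmox1 at 1.95 ± 0.169; the median was -0.08 while the mean of 0.24 and the test were positive (camera adjusted p = 0.793). Of 29 genes of cholesterol and lipid synthesis 4 rose and 13 fell, among them the elongase Elovl6 (-1.56 ± 0.125) and Insig1 (-0.88 ± 0.075), with a camera adjusted p of 0.0215 and adjusted p = 0.605 with an estimated correlation.

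Genes of mitochondrial function went both ways. Of 13 mitochondrially encoded protein genes 2 rose and 2 fell, such as mt-Cytb (-0.50 ± 0.102). The rise of mt-Co1 (0.42 ± 0.11, adjusted p = 0.00897) did not pass without MitoPositive D (0.0514) or without letter C (0.0747). Of 75 respiratory chain genes 4 rose and 12 fell, of 77 mitochondrial ribosome genes 13 and 6, of 42 biogenesis and dynamics genes 9 and 9, of 22 citric acid cycle genes 3 and 6, and of 24 fatty acid oxidation genes 10 and 4; none of these sets passed camera (adjusted p = 0.741 for the encoded proteins, then 0.328, 0.876, 0.793, 0.336 and 0.489). The ribosomal RNAs mt-Rnr1 (1.70 ± 0.0903) and mt-Rnr2 (0.90 ± 0.118) rose. The RNA composition list had a camera adjusted p of 0.0281, and adjusted p = 0.471 with an estimated correlation. Both RNAs were counted after ribosomal RNA depletion, and a difference in depletion between the groups was not excluded. Of 37 adhesion, cytoskeleton and nanotube genes 12 rose and 14 fell: Tubb6 (2.48 ± 0.218), Myo10 (2.26 ± 0.157) and Tln2 (1.30 ± 0.185) rose, and the actin crosslinker Actn1 (-1.68 ± 0.113) and Tln1 (-0.55 ± 0.0669) fell (camera adjusted p = 0.572).

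Interferon response genes were higher, with 31 of 39 members up and none called lower by edgeR; limma voom called 25 and DESeq2 31. Mx2 rose 31.1-fold (4.96 ± 0.739). The summed CPM of the list was 8594, 6447 and 6198 in MitoPositive and 4550, 4230 and 4545 in monoculture for B, C and D, so letter B stood above the other letters in co-culture (camera adjusted p = 2.65e-09, and adjusted p = 0.471 with an estimated correlation). Of 38 stromal markers 32 were higher and 1, Tpm1, was lower; 16 had 0 counts in monoculture. Against a floor of 3 counts over the monoculture group (0.0165 CPM, counting error only), the collagen gene Col1a2 was at least 255-fold higher and the chemokine Ccl2 at least 187-fold higher. With such genes at their bound the median of the list was 4.75 on the log2 scale, against 6.17 as fitted (camera adjusted p = 5.07e-13, and adjusted p = 0.241 with an estimated correlation). Other large rises were Ak1 (7.71 ± 0.438, 5.02 against 0.022 CPM), Ifi204 (7.18 ± 0.883, uncertain because the Ifi200 family has similar copies) and the mitochondrial creatine kinase Ckmt1 (6.20 ± 0.583).

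Of 14 B-cell markers 11 fell (12 adjusted over the list alone), with Ighd at -2.74 ± 0.229 and Cd79a at -2.45 ± 0.302 (camera adjusted p = 6.45e-09, and adjusted p = 0.241 with an estimated correlation). Of 10 dendritic and class II markers 5 fell, with H2-Aa at -3.13 ± 0.271, and 1, Zbtb46, rose (camera adjusted p = 0.0913, and adjusted p = 0.653 with an estimated correlation). With the block the dendritic and class II list had adjusted p = 0.00103, and adjusted p = 0.154 with an estimated correlation as well. The B-cell genes Fcmr (-3.79 ± 0.219) and Cd22 (-3.18 ± 0.275) were among the largest falls, together with the prohormone convertase Pcsk1 (-3.95 ± 0.199) and Rnf144a (-3.35 ± 0.152). Of 16 CD8+ T-cell markers 12 fell, such as the receptor modulators Cd5 (-1.75 ± 0.0945) and Cd6 (-1.12 ± 0.0597), with a camera adjusted p of 5e-06 for the list and adjusted p = 0.241 with an estimated correlation. Cd8a differed by less than its standard error (0.03 ± 0.0832, adjusted p = 0.773). Of 12 myeloid markers 3 rose and 5 fell, of 5 CD4+ T-cell markers 0 and 1, of 5 natural killer cell markers 1 and 3, of 24 histone genes, which are near-identical and uncertain, 5 and 3, and of 81 cytosolic ribosomal protein genes 2 and 1, and these sets did not pass camera (adjusted p = 0.64, 0.876, 0.741, 0.741 and 0.878). Of 32 proliferation genes 1 rose and 4 fell, with a median of -1.02 (camera adjusted p = 0.0139, and adjusted p = 0.914 with an estimated correlation). With the block 1 proliferation gene rose and 25 fell, and DESeq2 called 12.

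The comparison of MitoNegative cells with monoculture asked how co-cultured T cells without the label differed from T cells cultured alone. The same named genes of effector function, p53 response and glycolysis were higher: Cdkn1a rose 23.3-fold (4.54 ± 0.147), Ifng 17.6-fold (4.14 ± 0.482), Gzmb 13.3-fold (3.74 ± 0.352) and Pgk1 4.69-fold (2.23 ± 0.11). Klf2 (-3.91 ± 0.191) and Tcf7 (-0.63 ± 0.102) fell. The mitochondrial ribosomal RNAs rose, mt-Rnr1 6.62-fold (2.73 ± 0.0937) and mt-Rnr2 2.60-fold (1.38 ± 0.119). The RNA composition list had a camera adjusted p of 0.000213, and adjusted p = 0.218 with an estimated correlation. These RNAs were counted after ribosomal RNA depletion, and a difference in depletion between the groups was not told apart from a difference in the cells.

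In this comparison 6110 genes passed, 3233 higher and 2877 lower, of which 1289 and 362 differed by more than 2-fold. Without the libraries of letter C the count was 3495. Camera called 18 of 31 lists, 11 higher and 7 lower, and none held with an estimated correlation (smallest adjusted p = 0.0697, for the naive and stem-like memory and the apoptosis and p53 lists), while fry called 17.

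Of 27 apoptosis and p53 genes 17 rose and 3 fell, with Phlda3 at 2.59 ± 0.0594. Of 22 naive and stem-like memory genes 2 rose and 15 fell, among them Id3 (-1.89 ± 0.145) and Slamf6 (-1.32 ± 0.0769). Of 30 effector and cytotoxic genes 18 rose and 2 fell (camera adjusted p = 5.45e-07, and adjusted p = 0.201 with an estimated correlation), and of 29 genes of T-cell receptor activation 17 rose and 1 fell (camera adjusted p = 6.04e-10, and adjusted p = 0.218 with an estimated correlation). Of 22 inhibitory receptor and exhaustion genes 10 rose and 1 fell: Havcr2 had 2.63 ± 0.276 and Pdcd1 1.63 ± 0.196 (camera adjusted p = 0.00129, and adjusted p = 0.26 with an estimated correlation). Tox had an adjusted p of 0.138, and 0.0414 with the block. Of 24 chemokine and cytokine receptors 12 rose and 4 fell (camera adjusted p = 0.0157, and adjusted p = 0.218 with an estimated correlation). Of 39 interferon response genes 33 rose and none was called lower by edgeR (29 called by limma voom, 35 by DESeq2); Mx2 had 5.31 ± 0.743, and letter B stood highest with a summed 9906 CPM against 7330 and 6819 CPM in C and D (camera adjusted p = 4.27e-15, and adjusted p = 0.26 with an estimated correlation).

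Of 25 glycolysis genes 16 rose and 1 fell, with Hk2 at 1.34 ± 0.15 (camera adjusted p = 1.28e-09, and adjusted p = 0.201 with an estimated correlation). Of 33 ATF4 stress response genes 23 rose and 2 fell (camera adjusted p = 3.41e-12, and adjusted p = 0.236 with an estimated correlation), with Slc1a4 at 3.72 ± 0.261. Of 20 hypoxia targets 9 rose and 2 fell, with Vegfa at 2.94 ± 0.176 (camera adjusted p = 0.000631, and adjusted p = 0.218 with an estimated correlation). Of 29 genes of cholesterol and lipid synthesis 4 rose and 14 fell (camera adjusted p = 0.00677, and adjusted p = 0.497 with an estimated correlation). Of 13 mitochondrially encoded protein genes 4 rose, mt-Co1 among them (0.64 ± 0.11, 1.56-fold), and 1 fell; the list's median was -0.09 while its mean of 0.03 and its test were positive (camera adjusted p = 0.869). Of 75 respiratory chain genes 5 rose and 20 fell, such as Atp5a1 (-0.42 ± 0.0843); the set was lower by camera (adjusted p = 0.0398), a call that ended with the block (0.0737) and with an estimated correlation (adjusted p = 0.896). Of 32 proliferation genes 7 fell, such as Mcm6 (-0.59 ± 0.0645), and with the block 1 rose and 27 fell, among the latter Mki67 (-1.53, adjusted p = 0.000892 with the block and 0.14 without it), with a camera adjusted p of 0.00145 and adjusted p = 0.758 with an estimated correlation. Of 81 cytosolic ribosomal protein genes 2 rose, and 6 with the block. Of 77 mitochondrial ribosome genes 10 rose and 11 fell, of 42 biogenesis and dynamics genes 9 and 8, of 22 citric acid cycle genes 1 and 7, of 24 fatty acid oxidation genes 9 and 5, of 20 unfolded protein response genes 6 and 1, of 22 oxidative stress genes 6 and 8, and of 37 adhesion, cytoskeleton and nanotube genes 7 and 15. These sets did not pass camera (smallest adjusted p = 0.0963, for the adhesion list).

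Of 38 stromal markers 32 were higher and 1 lower. Col1a2 was at least 306-fold higher and Ccl2 at least 224-fold higher than the same floor in monoculture, Fn1 rose by 7.03 ± 0.815 on the log2 scale, and the median with such bounds was 4.76 (camera adjusted p = 9.1e-17, and adjusted p = 0.218 with an estimated correlation). The cytokine Il6 rose by 5.74 ± 0.665, from 0.116 to 6.27 CPM. Of 14 B-cell markers 10 fell (camera adjusted p = 4.35e-08, and adjusted p = 0.26 with an estimated correlation), and Fcrla, a B-cell gene, had -2.62 ± 0.292. Of 16 CD8+ T-cell markers 13 fell (camera adjusted p = 2.44e-06, and adjusted p = 0.218 with an estimated correlation), while Cd8a had 0.11 ± 0.0832 and an adjusted p of 0.313. Of 10 dendritic and class II markers 1 rose and 5 fell, with H2-Aa at -2.95 ± 0.268 (camera adjusted p = 0.0413, and adjusted p = 0.555 with an estimated correlation). Of 12 myeloid markers 3 rose and 4 fell, of 5 natural killer cell markers 2 and 1, and of 24 histones 8 and 2; edgeR called 0 of 5 CD4+ T-cell markers (2 with an unadjusted p under 0.05, 2 by DESeq2, 0 by limma voom; 1 higher with the block). Ptprc had -0.21 ± 0.0787, with an adjusted p of 0.0507 and of 0.0487 with the block.

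Both comparisons with monoculture called 5245 genes in the same direction, 2783 higher and 2462 lower, and 0 in opposite directions. Independent lists of these sizes would share 1295. Over 20 simulations, 9 unchanged libraries drawn from the monoculture means, with no effect of the letter, shared 0.15 on average and at most 2. With no gene changed few calls can arise, so this does not show what shared controls add when many genes differ. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.961, against 0.512 in the simulations, and a covariance of 0.942, against 0.0505, a difference of 0.892. The 3 monoculture libraries were too few to split, so part of the overlap may come from the shared controls. Stromal RNA in both co-cultured groups may add to it as well. The summed CPM of 27 stromal markers was 41.3 in MitoNegative and 37.7 in MitoPositive, against 0.276 in monoculture. The summed CPM of the 14 B-cell markers was 728.6, 707.7 and 778.4 in monoculture for letters B, C and D. It was 431.4, 473.7 and 375.6 in MitoNegative and 283.6, 315.2 and 319.4 in MitoPositive. How many of the shared calls come from RNA of stromal cells or B cells, and not from T cells, was not tested. Without the libraries of letter C the shared calls numbered 3093.

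**Figure D2:**
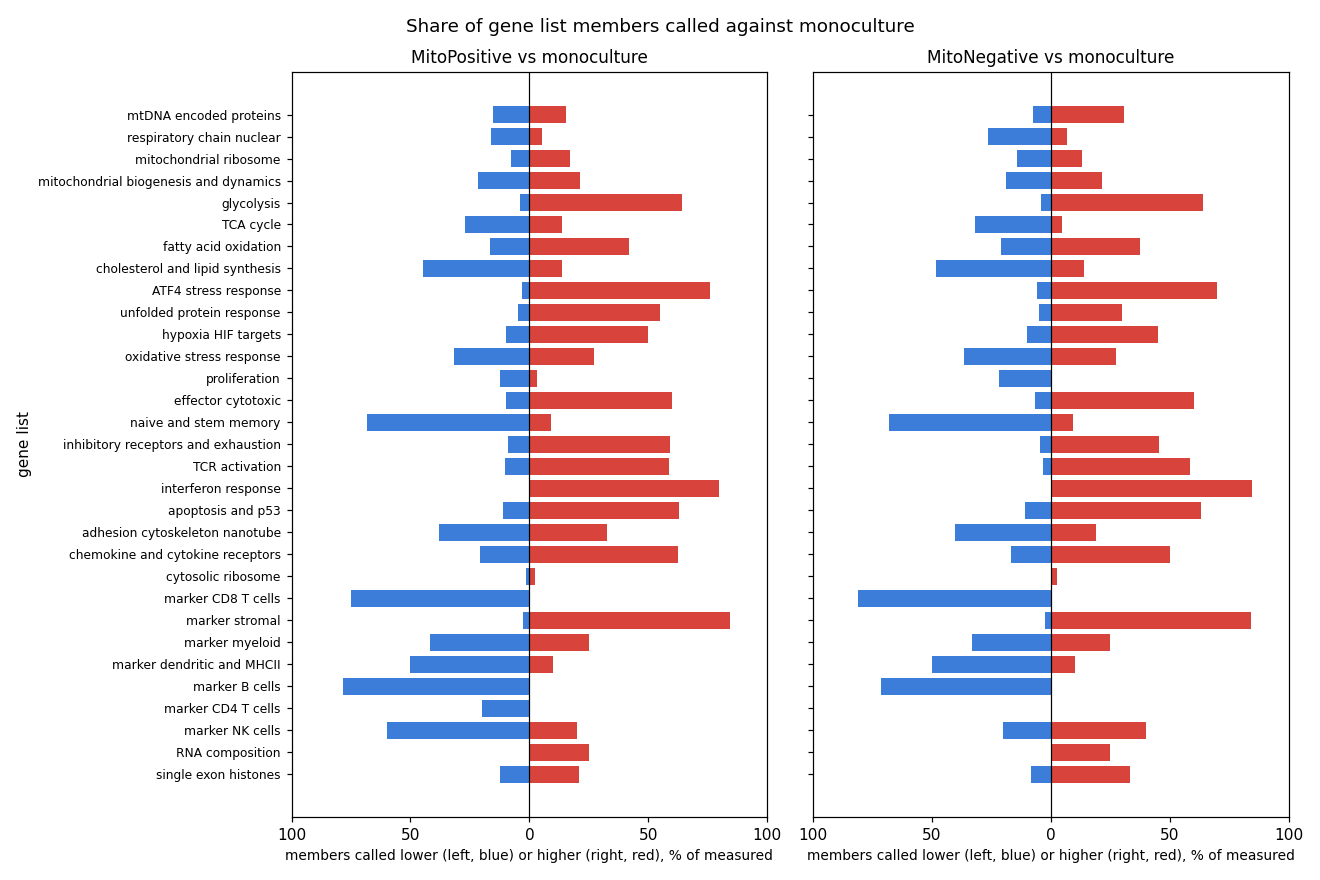
Percent of the measured members of each gene list called higher (red, right) or lower (blue, left) than monoculture by edgeR, for MitoPositive (left panel) and MitoNegative (right panel). Stromal markers reach 32 of 38 members higher in each panel, and B-cell markers 11 and 10 of 14 members lower.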

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

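The tests of mitochondrial RNA amount, ribosomal RNA depletion, stromal RNA and mixed cells were chosen after the results were seen. The 21 genes named by the fixed rule that passed between MitoPositive and MitoNegative are listed because the change from monoculture differed between both co-cultured groups by a test of that difference itself. On the log2 scale the differences were 0.8696 for Serpine2, 0.8292 for Tnfsf4, 0.8125 for Prdm1, 0.7884 for Cdkn1a, 0.6276 for Glipr1, 0.4985 for Inka2, 0.4866 for Phlda3, 0.478 for Raph1, 0.4622 for Slamf7, 0.4168 for Zmat3 and 0.3996 for Icos. The negative differences were -0.3158 for Ifnar2, -0.3478 for Coro7, -0.4845 for Arl5c, -0.5024 for Pik3ip1, -0.5181 for Ighm, -0.5605 for Tbc1d4, -0.5798 for Smc4, -0.7268 for Nsg2, -1.028 for mt-Rnr1 and -1.03 for Rnf144a.

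The first pattern was the lower mt-Rnr1 in MitoPositive cells. A lower amount of mitochondrially encoded RNA in general would lower the 13 protein genes alike, but their summed CPM had a log2 ratio of -0.189 (SE 0.0879 over 3 letters), which argues against it as the whole cause. Better ribosomal RNA depletion in the MitoPositive libraries stays open. Gm42418, which overlaps a ribosomal RNA repeat, had log2 ratios of 2.1, -1.03 and 0.149 in letters B, C and D, with a mean of 0.408 (SE 0.912). It is not a mitochondrial ribosomal RNA, so it cannot decide this for mt-Rnr1. By edgeR mt-Rnr2 had -0.479 ± 0.117 (adjusted p = 0.125), and -0.487 ± 0.0881 with the block (adjusted p = 0.0222). A difference in mitochondrial ribosomal RNA between the sorted cells also stays open and was not tested further.

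The second pattern was the set of genes higher in MitoPositive than in MitoNegative cells. More stromal cells or stromal RNA in the MitoPositive libraries would raise stromal markers by at least the smallest called rise, 0.342. The summed CPM of 27 stromal markers near 0 in monoculture had a log2 ratio of -0.14 (SE 0.0536), with 41.3 CPM in MitoNegative and 37.7 CPM in MitoPositive cells, against 0.276 CPM in monoculture, which argues against this explanation. A difference between cells with and without the label stays open.

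The third pattern was that 23 of the 26 genes called between the sorted groups continued the direction from monoculture to MitoNegative. Of the 367 called with the block 263 did, and 60 were called in the opposite direction. Both comparisons use the same MitoNegative libraries, whose noise alone favours opposite directions, and no value without a change was computed for these counts. If MitoPositive cells lay further along the co-culture change, each letter would have a positive slope on the change measured in the other letters. The slopes were 0.0705, 0.0912 and 0.0243 for B, C and D, with correlations across genes of 0.137, 0.182 and 0.0571. All were positive, the sign this explanation needs. No value without a change was computed for the slopes, so the sign in 3 letters does not show this explanation. A mix of cells, described next, would give positive slopes as well, so the slopes do not tell these explanations apart. If MitoNegative libraries were a mix of MitoPositive-like and monoculture-like cells, MitoNegative would lie between the other groups. By the larger p of its tests against both, with the block and adjusted over 15711 genes, 2 genes lay outside, mt-Rnr1 and Klrc1, the latter chosen after its values were seen (adjusted p = 0.00315 and 0.0116). Without letter B or C edgeR gave 0 (339 and 221 with an unadjusted p under 0.05) and without D 42. The number depended on letters, and 2 was under a limit set after the results were seen, so for most genes a mix stays open. A mix alone would not place mt-Rnr1 2.73 above monoculture and 1.03 above MitoPositive (log2), unless depletion differed. In the interferon list 38 of 39 members were above monoculture in MitoNegative and 38 were lower in MitoPositive than in MitoNegative. None of these members passed between the sorted groups without the block, and 3 were lower with it. The members were correlated (estimated correlation 0.675) and both comparisons use the MitoNegative libraries. These signs therefore do not decide against a mix. With an estimated correlation that list did not pass in either comparison.

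The 10 splits of 3 against 3 libraries were too few for a share under 0.05. In fits of the compared groups alone the real split called 65 genes between MitoPositive and MitoNegative, 5975 between MitoPositive and monoculture and 5366 between MitoNegative and monoculture. The highest count by edgeR in another split was 0 in each, so 1 split, the real one, reached each count, and the other splits had up to 1744, 627 and 608 genes with an unadjusted p under 0.05. The 4 splits that part the letters were also too few; with the block the real split called 2810 genes and the highest other 0, with up to 266 at an unadjusted p under 0.05, so 1 split reached it. For gene lists the real splits called 16, 18 and 17 lists, and the highest other splits 17, 17 and 16; 3, 1 and 1 splits of 10 called as many.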

How the results depend on the processing

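The alternatives to the count with the replicate block, and the estimated correlation together with the block, were chosen after seeing the data. Between MitoPositive and MitoNegative 26 genes passed; 15 did with RLE size factors, 14 with total counts, 171 without a filter, 412 with DESeq2, 68 with limma voom, 65 with the compared groups alone and 367 with the block. Of the 26, these settings shared 15, 13, 25, 24, 25, 25 and 26; the cause was not tested. Leaving out libraries or letters gave 0 to 120 genes, with 0 by edgeR without letter B or C. With the block 367 passed, 365 with RLE, 580 with DESeq2 and 2810 with the compared groups alone, and leaving out a letter gave 0 (B and C, with 1303 and 994 at an unadjusted p under 0.05) to 969 (D). The cause was not tested beyond the fewer libraries in these fits.

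Leaving out libraries or letters gave 4122 (letter C) to 6695 genes between MitoPositive and monoculture, 3495 (letter C) to 6037 between MitoNegative and monoculture, and 3093 (letter C) to 5238 shared by both. Other settings stayed within 1.5-fold, with 7508 and 7062 genes under the block. Lists called with an estimated correlation numbered 0 between MitoPositive and MitoNegative (smallest adjusted p = 0.0961), 2 between MitoPositive and monoculture and 0 between MitoNegative and monoculture, and fry called 0 in the first; with the block as well an estimated correlation called 0, 0 and 0. An estimated correlation within a list widens its test by construction; for fry the cause was not tested. Leaving out libraries gave 14 to 17, 13 to 18 and 16 to 20 lists. The block ended the calls of the unfolded protein and RNA composition lists between MitoPositive and monoculture (adjusted p = 0.0776 and 0.0521) and added the dendritic and class II list (from adjusted p = 0.0913 to 0.00103), and it gave 1 higher and 25 lower proliferation genes there.

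Of 4944 values of 236 gene results, 4629 kept their direction and side of the threshold, 279 no longer passed, 15 newly passed and 21 changed sign; those 21 belong to genes that were not called. The log2 fold change of Tln1, MitoPositive vs MitoNegative, was 0.01302 with total counts, 0.01064 without a filter, 0.001652 with the authors' genes, 0.0009064 with the compared groups alone and 0.001848 without mitochondrially encoded genes, and from -0.03492 to 0.02466 with libraries left out. With libraries left out, the log2 fold change of Col1a1, MitoPositive vs MitoNegative, went from -0.4671 to 0.2602, the log2 fold change of Cd8a, MitoPositive vs monoculture, from -0.03339 to 0.09386, and the log2 fold change of Tfam, MitoNegative vs monoculture, from -0.03651 to 0.09905. The log2 change of mt-Rnr1 between the sorted groups was -1.07 to -0.97 over the settings, and its call ended without letter B (adjusted p = 0.104) or C (0.347), which leaves fewer libraries. On simulated data the fit without the block found 47.8% of 1.5-fold changes, with the spread estimated without the letter. A difference of that size can therefore be missed by that fit at this depth and number of libraries. The fit with the block was not simulated.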

Other observations

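The slopes named here were planned before the result was seen. Shares of counts per library (mean ± SD, n = 3) described the make-up of the RNA. Mitochondrially encoded protein genes took 1.91% ± 0.22 in MitoPositive, 2.15% ± 0.16 in MitoNegative and 1.63% ± 0.13 in monoculture. Cytosolic ribosomal proteins took 12.8% ± 0.77, 13.3% ± 0.5 and 12.5% ± 1.6, and the 10 largest genes 6.62% ± 0.38, 6.92% ± 0.3 and 6.01% ± 0.51. Stromal markers took 0.0112% ± 0.0011, 0.0117% ± 0.001 and 0.00621% ± 0.00038. That share sums the whole list, of which some members were not near 0 in monoculture. The 27 members near 0 there summed to 0.276 CPM in monoculture, 41.3 CPM in MitoNegative and 37.7 CPM in MitoPositive. None of the 18 exact two-sided permutation tests of such shares passed (smallest p = 0.1, the smallest possible here, adjusted p = 0.257). These tests did not pair the letters. Within each letter, each share named here was lower in MitoPositive than in MitoNegative.

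Among genes with a change over 2-fold from monoculture to MitoNegative, measured in the other letters, the change from MitoNegative to MitoPositive had the same direction in 61.3% of 1852 genes for letter B, 62.4% of 1993 for C and 55% of 1997 for D. The lowest of the 3 slopes was 0.0243.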
